A study of Mus musculus with 28 samples.

How the data were processed

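RNA from the gastrocnemius, plantaris and soleus of 28 female FVB mouse muscle samples had been extracted with TRIZOL and cleaned on RNeasy columns, amplified by T7 linear amplification, labelled with biotin and hybridised to Illumina expression BeadChips, per the labels' protocols. Samples were assigned to 4 groups of 7 from their titles: wild type at rest, wild type after contraction, muscle-specific LKB1 knockout at rest and knockout after contraction.

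The values deposited by the authors are probe intensities on a linear scale for 25697 probes and 28 arrays. They range from -36.1 to 50215 with 27.2% of values below 0, so a background had already been subtracted, and nearly equal quantiles in every column show that they had been quantile-normalized between arrays. R 3.1.2, lumi 3.0 and limma 3.1 are named in the submitters' processing notes, with no role or order. A second deposited table holds non-normalized intensity values and, per the file headers, a detection p-value for each probe. Its 28 intensity columns are numbered without a gap, whereas the sample numbers in the labels skip some after 7 and run past 28. Only the 7 columns before the first skip, those of resting wild type, were therefore assigned to samples. The other 21 were not used, and no column was assigned by its values. For this reason the plan to start from the non-normalized values with limma's neqc was given up, and the deposited normalized intensity values became the starting point. Quantile normalization forces 1 distribution on all arrays, so a shift of most genes in the same direction would not be visible.

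The normalized intensities were corrected with limma's normexp at an offset of 50 and set on a log2 scale, which shrinks differences of dim probes towards 0. On the 7 matched arrays the normalized intensity and the detection p-value of a probe could be set side by side, and the median intensity at a detection p-value of 0.05 was 23.9, which was taken as the dim limit. A stricter limit of 45.0 was read in the same way at a detection p-value of 0.01. Probes above the dim limit on at least 7 of 28 arrays were kept, 11725 in all. The annotation table gave 1 gene symbol for 23978 of the 25697 probes, several for 0 and none for 1719, and 11075 kept probes had a symbol. A gene was represented by its probe with the highest mean over all arrays, which gave 8391 genes, 2013 of them with more than 1 kept probe. Between 36.0% and 43.1% of the probes had been detected on the 7 matched arrays. The number of arrays limits the precision.

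A linear model with a mean for each of the 4 groups was fitted to all 28 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and jsonlite 2.0.0 read the labels. The 5 comparisons were contraction in wild type, contraction in knockout, knockout against wild type at rest, knockout against wild type after contraction, and the difference of the contraction responses. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, with no fold threshold. Values given as changes are log2 differences, and SE is limma's moderated standard error. The comparisons, their tests, the rule for named genes and the gene lists were fixed before the data were examined, apart from the starting values named above. Part of the alternatives and of the tests of explanations was added later, as the closing section says.

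The 32 gene lists held 771 genes, 543 of them measured, and each tested list had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, Benjamini-Hochberg adjusted over the 32 lists of a comparison. With an estimated correlation 3 of the 45 camera calls held, all 3 of them in contraction of knockout muscle. Lists marking other cell types were included because the whole muscle complex holds them: macrophage, neutrophil, lymphocyte, red blood cell, endothelial, fibroblast, adipocyte, Schwann cell and satellite cell markers, besides slow- and fast-fibre genes.

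The genes named are, for each comparison, the 10 largest rises and the 10 largest falls among the called genes, up to 4 members with the smallest p of each list with a camera adjusted p under 0.05, and in every comparison Stk11, Fos, Egr1, Il6, Ppargc1a, Nr4a3, Pdk4, Slc2a4, Prkaa2 and Hspa1b where measured. Where fewer than 5 genes passed, the 5 with the smallest p are given as values. Applying the rule to the blocked fit of contraction in knockout was decided after the data had been seen.

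The labels number the samples 1 to 7 in each group. Whether equal numbers pair the resting and contracted samples of a genotype was checked from the correlation, across genes, of their deviations from the group means. In knockout all 7 pairs had a correlation over 0.1, from 0.37 to 0.85 (mean 0.657, exact permutation p = 0.000198 over 5040 orders), so the fit with the number as a block is given beside the unblocked one there. The pairing rests on this correlation and not on a label. In wild type 5 of 7 pairs were over 0.1 (mean 0.264, p = 0.0183 by the same permutation), and across genotypes 4 of 7 at rest (mean 0.17, p = 0.0393) and 3 of 7 after contraction (mean 0.00063, p = 0.494). Since not every pair was over 0.1, the numbers were not taken to pair those samples, although the first 2 means were above those of most other orders. No slide or scan date was given in the sources used here, so batches could not be examined.

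The scripts were tested on simulated data in which 50 genes for each fold size were changed among 8391. At folds of 1.2, 1.5, 2 and 3, contraction in wild type recovered 4%, 62%, 94% and 100% of them, contraction in knockout 8%, 60%, 94% and 98%, contraction in knockout with the block 12%, 82%, 96% and 100%, knockout at rest 16%, 62%, 96% and 98%, knockout after contraction 14%, 66%, 98% and 100%, and the difference of responses 2%, 34%, 86% and 94%. Between 0 and 8 of the 8191 unchanged genes were called. The changed genes were drawn at random, with normal noise of each gene's own spread. The shares recovered therefore describe a typical gene, and not genes of larger spread such as Fos, Rrad or Cxcl1. A list raised in the simulation of knockout at rest was called by camera with both correlations and by fry, and 0 other lists were called by camera. In all these simulations genes were drawn independently of each other. False calls of genes or lists that come from correlation between genes were therefore not tested. The 0 to 8 false calls are no error rate for the real arrays, where another split of the knockout samples called 1617 genes.

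Alternatives covered the background offset, a floor in place of normexp, cyclic loess, the filter on dim probes, the choice of probe, the arrays in the fit, array weights, the replicate block, the spread estimate, the thresholds, and leaving out single samples or samples that stood apart in slow-fibre or lymphocyte genes.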

Results

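Gene expression was measured in the calf muscle complex (gastrocnemius, plantaris and soleus together) of 4-month-old female FVB mice that were either wild type or lacked LKB1 in skeletal muscle only. LKB1, encoded by Stk11, is the kinase that activates AMPK and the AMPK-related kinases. Muscles were unstimulated or had just contracted for 15 min, driven in situ through the sciatic nerve. The 28 samples formed 4 groups of 7: resting wild type, contracted wild type, resting knockout and contracted knockout. One Illumina bead array was hybridised per sample, 25697 probes were read, and 8391 genes were bright enough to be tested. Between 41.2% and 41.6% of the probes of each array lay above the dim limit. Quantile normalization makes these shares nearly equal, so they do not compare the quality of the arrays. For the 7 resting wild-type arrays, un-normalized intensities could also be matched to samples, and there the mean intensity per array ranged from 201 to 446. The number of arrays limits the precision of every value: the median standard error of a log2 difference between groups was 0.13. The labels number the samples of each group from 1 to 7 without saying whether equal numbers share an animal, and the p-values measure the spread between these samples.

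Stk11 itself was lower in each of the knockout samples than in any wild-type sample. At rest its log2 intensity was 8.96 ± 0.32 (SD, n = 7) in knockout and 10.32 ± 0.20 (SD, n = 7) in wild type, a level of 38.9% of wild type. After contraction it was 8.97 ± 0.22 (SD, n = 7) in knockout and 10.45 ± 0.16 (SD, n = 7) in wild type, a level of 35.9%. Stk11 fell by 1.36 on the log2 scale at rest (SE 0.12, limma adjusted p = 1.08e-07) and by 1.48 after contraction (SE 0.12, limma adjusted p = 1.67e-08). The exact two-sided permutation test gave p = 0.000583 in both states, the smallest p that 7 against 7 samples allow. The highest knockout sample was at 9.32 and the lowest wild-type sample, contracted sample 4, at 10.10. Contraction left Stk11 within its error, with differences of 0.12 (SE 0.12) in wild type and 0.01 (SE 0.12) in knockout. Where the probe lies relative to the deleted exons is not given in the sources used here, so the level left in the knockout is a probe signal and not an amount of intact transcript.

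**Figure D1:**
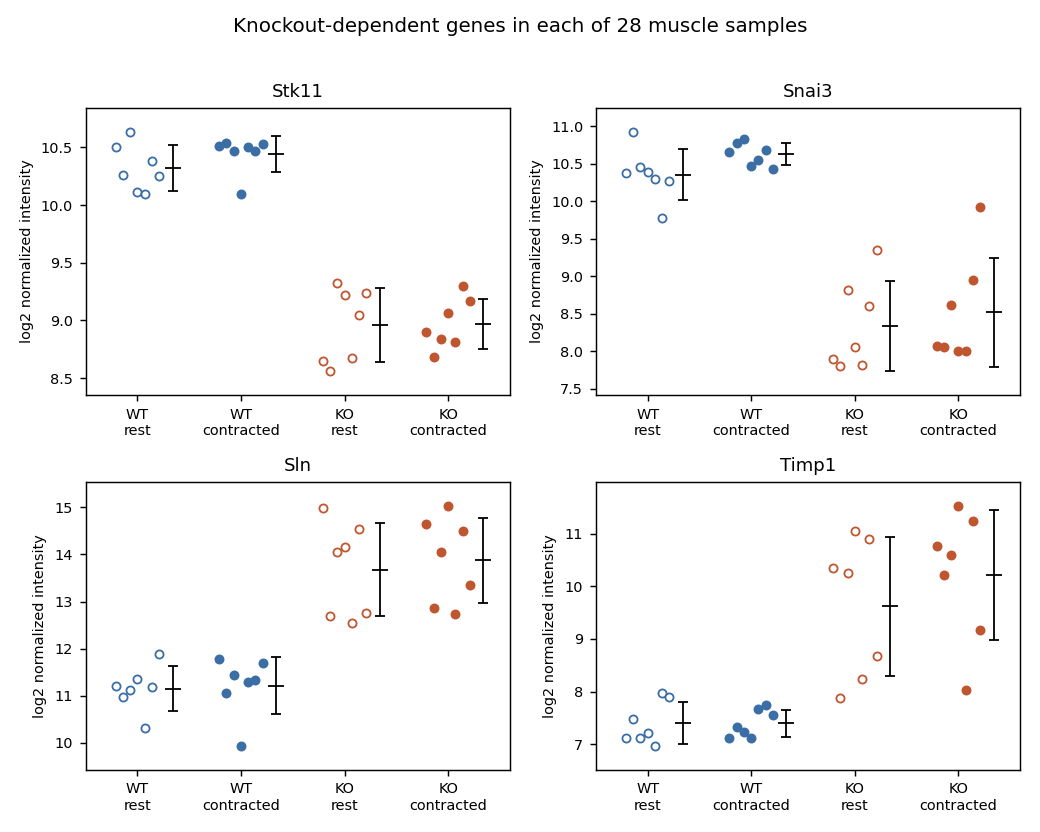
Log2 normalized intensity of Stk11, Snai3, Sln and Timp1 (vertical axes) in the 4 groups (horizontal axes; WT wild type, KO knockout); each circle is 1 of the 28 samples, open at rest and filled after contraction, and the bars give the mean and SD of 7 samples. No knockout sample reaches 10.10, the lowest wild-type value of Stk11, and Sln is above its resting wild-type range in all 7 resting knockout samples.

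The first comparison asked what loss of LKB1 did to unstimulated muscle. In resting knockout muscle 8 of 16 genes known from denervated or regenerating muscle rose, and 5 of 40 oxidative phosphorylation subunits and 4 of 16 tricarboxylic acid cycle genes fell. Of the 7 lists that camera called at rest, 0 held with an estimated correlation, where the lowest adjusted p was 0.284. Sln, a peptide inhibitor of the sarcoplasmic reticulum calcium pump, rose by 2.53 on the log2 scale (SE 0.39, limma adjusted p = 0.000815), and Ankrd1, a stretch-responsive ankyrin repeat protein of muscle, rose by 2.19 (SE 0.42, adjusted p = 0.00425). A second, dimmer probe of Ankrd1 was at 0.52 with an unadjusted limma p of 0.0211. Snai3, a member of the Snail family of transcriptional repressors, fell by 2.02 (SE 0.26, adjusted p = 5.87e-05). Irs2, an adaptor of insulin signalling, fell by 1.46 (SE 0.32, adjusted p = 0.013). In all, 316 of 8391 genes passed an adjusted p of 0.05, of which 153 rose and 163 fell, and 45 of them changed by more than 2-fold.

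The denervation, regeneration and embryonic myosin list had 16 measured members, of which 8 rose, 0 fell and 13 rose when adjusted over the list alone. Besides Sln and Ankrd1, the members with the smallest p were Cdkn1a, a cyclin-dependent kinase inhibitor, which rose by 1.33 (adjusted p = 0.00109), and Chrnb1, a subunit of the muscle acetylcholine receptor, which rose by 1.09 (adjusted p = 0.00695). Chrng, the fetal subunit of that receptor, rose by 1.59 (SE 0.45, adjusted p = 0.0428) and the adhesion molecule Ncam1 by 1.53 (SE 0.36, adjusted p = 0.0181). The list's median difference was 1.09 (camera adjusted p = 1.67e-11; adjusted p = 0.284 with an estimated correlation). The other genes among the 10 largest rises were Timp1, a secreted inhibitor of matrix metalloproteinases, at 2.22 (SE 0.47, adjusted p = 0.00857), Tekt1 at 1.99, Aldh3a1 at 1.98, Cpne2 at 1.91, Tmem100 at 1.87 and Clca4a at 1.70. Timp1 was the 1 member of the 24 fibroblast and matrix genes that passed, over all genes and over the list alone. Lum, a matrix proteoglycan, and Loxl1, a collagen cross-linking enzyme, had differences of 0.91 and 0.56 that missed the threshold. The fibroblast and matrix list had a median of 0.32 (camera adjusted p = 0.00012; adjusted p = 0.461 with an estimated correlation).

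Of the 40 measured oxidative phosphorylation subunits, 5 fell, 0 rose and 8 fell when adjusted over the list alone. Cox8b fell by 0.50 (SE 0.11, adjusted p = 0.00796), Ndufs8 by 0.50 (SE 0.10, adjusted p = 0.00823), Ndufa8 by 0.31 and Atp5g1 by 0.23. The median of the list was -0.18 (camera adjusted p = 7.44e-06; adjusted p = 0.284 with an estimated correlation). Of 16 tricarboxylic acid cycle genes 4 fell, 6 when adjusted over the list alone: the isocitrate dehydrogenase genes Idh2, Idh3a and Idh3g fell by 1.17, 0.59 and 0.24 and the malate dehydrogenase gene Mdh1 by 0.46. A second, dimmer probe of Idh3g was at -0.06 with an unadjusted limma p of 0.786. The median of the cycle genes was -0.19 (camera adjusted p = 0.00348; adjusted p = 0.284 with an estimated correlation). Among 26 genes of fatty acid uptake and oxidation, Echs1, an enoyl-CoA hydratase, fell by 0.74 (SE 0.18, adjusted p = 0.0188), and 10 members fell when adjusted over the list alone. Acads and Acadl, acyl-CoA dehydrogenases, were at -0.75 and -0.85 and missed the threshold over all genes. A second, dimmer probe of Acadl was at 0.14. The list's median was -0.34 (camera adjusted p = 0.00012; adjusted p = 0.369 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial gene expression, fell by 0.70 (SE 0.18, adjusted p = 0.0262).

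The remaining genes among the 10 largest falls were Kcnc1, a voltage-gated potassium channel, at -1.26 (SE 0.22, adjusted p = 0.00265), Vamp5, a vesicle membrane protein of muscle, at -1.18 (SE 0.21, adjusted p = 0.00265), the phosphatase Dusp26 and the iron exporter Slc40a1, both at -1.14, Nrep at -1.11 and Magix at -1.10. Dimmer second probes of Kcnc1 and Ncam1 were at -0.23 and 0.26, with unadjusted limma p of 0.0889 and 0.0927. The endothelial and mural cell list shifted down (median -0.21, 20 members, camera adjusted p = 0.00428; adjusted p = 0.461 with an estimated correlation). Ribosomal proteins shifted up (median 0.15, 22 members, camera adjusted p = 0.0379; adjusted p = 0.672 with an estimated correlation). In both lists 0 members passed over all genes or over the list alone. Without the 3 samples low in slow-fibre genes the ribosomal call ended (median 0.05, camera adjusted p = 0.393), and without the 5 samples high in lymphocyte markers the medians of the endothelial and oxidative phosphorylation lists were -0.14 and -0.12. Myh11, a smooth muscle myosin, and Flt1, a VEGF receptor, were at -0.56 and -0.44, and Rps2 and Rps12 at 0.45 and 0.39. Of the genes named in every comparison, Fos (0.77), Egr1 (0.61), Nr4a3 (-0.44), Pdk4 (0.16), Slc2a4 (-0.10) and Prkaa2 (-0.13) missed the threshold at rest. Il6 was above the dim limit on 2 of 28 arrays and was not tested, and Hspa1b has no probe here.

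The count of 316 was 109 without resting knockout sample 1, 168 without sample 6 and 676 without sample 7 of that group, and 206, 160, 190, 206 and 203 without resting wild-type samples 1, 2, 3, 6 and 7. Calls close to the threshold ended when 1 of the 28 arrays was left out. This held for 21 arrays for Dusp26 (highest adjusted p = 0.109), 16 for Mdh1, 14 for Chrng, 10 for Slc40a1, 6 each for Ppargc1a, Idh3g and Atp5g1, 4 for Tekt1, 3 each for Clca4a and Idh2 and 2 for Aldh3a1. The calls of Ncam1, Echs1 and Ndufa8 ended without resting knockout sample 1, at adjusted p of 0.0574, 0.0609 and 0.0645.

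The second comparison set knockout against wild type directly after contraction. In contracted knockout muscle 6 of 27 immediate-early genes, 5 of 16 heat shock and chaperone genes, 4 of 17 interferon-response genes and 11 of 16 denervation-associated genes rose, and 7 of 40 oxidative phosphorylation subunits fell. Of the 17 lists that camera called after contraction, 0 held with an estimated correlation, where the lowest adjusted p was 0.36. Rrad, a small GTPase that inhibits calcium channels, rose by 3.25 on the log2 scale (SE 0.66, limma adjusted p = 0.00348), the immediate-early transcription factor Fos by 2.16 (SE 0.46, adjusted p = 0.00476) and Socs3, a feedback inhibitor of cytokine signalling, by 2.08 (SE 0.62, adjusted p = 0.0347). Vegfa, the main angiogenic growth factor of muscle, fell by 1.15 (SE 0.23, adjusted p = 0.00326), and its second, dimmer probe was at -0.56 with an unadjusted limma p of 0.017. In all, 747 of 8391 genes passed, 383 rising and 364 falling, 91 of them by more than 2-fold.

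Of 27 immediate-early genes 6 rose and 1 fell, 9 and 1 when adjusted over the list alone. Beside Fos, Ier3 rose by 1.24 (SE 0.28, adjusted p = 0.00634) and Atf3 by 1.29 (SE 0.32, adjusted p = 0.0136), whereas the nuclear receptor Nr4a3 fell by 0.79 (SE 0.15, adjusted p = 0.00218). The immediate-early list had a median of 0.29 (camera adjusted p = 0.00202; adjusted p = 0.36 with an estimated correlation). Egr1 was at 1.01 (SE 0.52) and missed the threshold. Of 16 heat shock and chaperone genes 5 rose, and 5 rose and 2 fell when adjusted over the list alone: Dnajb1 by 0.91 (SE 0.14, adjusted p = 0.000394), Hspa1a by 1.54 (SE 0.35, adjusted p = 0.00741), Hspb8 by 1.03 and Hspb7 by 0.78. The chaperone list had a median of 0.18 (camera adjusted p = 0.0325; adjusted p = 0.36 with an estimated correlation). Among 13 MAPK phosphatases and feedback regulators 3 rose, 5 rising and 1 falling when adjusted over the list alone: Gadd45a by 1.56 (SE 0.36, adjusted p = 0.00852), Dusp4 by 0.95 and Spred1 by 0.72. Gadd45a is also a member of the denervation list. The phosphatase and feedback list had a median of 0.25 (camera adjusted p = 0.0435; adjusted p = 0.36 with an estimated correlation).

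Of 17 interferon-response genes 4 rose, 7 when adjusted over the list alone: the transcription factors Irf1, Irf9 and Stat2 by 1.34, 0.65 and 0.34 and the GTPase Igtp by 1.07. The interferon list had a median of 0.28 (camera adjusted p = 0.00322; adjusted p = 0.36 with an estimated correlation). Of 22 NF-kB pathway genes and targets 4 rose, also 4 when adjusted over the list alone: Tnip2 rose by 1.09 and Bcl3 by 0.46, beside Irf1 and Socs3. The NF-kB list had a median of 0.15 (camera adjusted p = 0.0241; adjusted p = 0.36 with an estimated correlation). Of 22 cytokines and chemokines 4 rose and 1 fell, 6 and 2 when adjusted over the list alone: Ccl9 by 1.03 (SE 0.23, adjusted p = 0.00588), Cx3cl1 by 1.06 (SE 0.26, adjusted p = 0.0127) and Cxcl14 by 0.80, with Vegfa the one that fell. The cytokine and chemokine list had a median of 0.18 (camera adjusted p = 0.0485; adjusted p = 0.371 with an estimated correlation). Of 12 macrophage and monocyte markers 2 rose, 3 when adjusted over the list alone: Lgals3, galectin-3, by 1.36 (SE 0.30, adjusted p = 0.00634) and Mrc1, the mannose receptor, by 0.90. The macrophage and monocyte list had a median of 0.44 (camera adjusted p = 0.0304; adjusted p = 0.405 with an estimated correlation). The 12 antigen presentation and complement genes had a median of 0.45 (camera adjusted p = 0.0485; adjusted p = 0.546 with an estimated correlation) with 0 past the threshold over all genes or over the list alone, H2-Eb1 being at 1.26 (SE 0.60) and C1qb at 0.52 (SE 0.25).

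Denervation-associated genes rose again, 11 of 16 (14 when adjusted over the list alone), with Ankrd1 at 2.85, Sln at 2.66, Cdkn1a at 1.45 and Chrnb1 at 1.17. The dimmer second probe of Ankrd1 was at 0.95 with an unadjusted limma p of 0.00015. The denervation list had a median of 1.13 (camera adjusted p = 5.84e-12; adjusted p = 0.36 with an estimated correlation). Fibroblast and matrix genes rose for 5 of 24 members, 9 when adjusted over the list alone: Timp1 by 2.82 (SE 0.47, adjusted p = 0.00119), Lum by 1.12, Fstl1, a secreted glycoprotein, by 0.92 and Loxl1 by 0.69. The matrix list had a median of 0.39 (camera adjusted p = 7.97e-06; adjusted p = 0.36 with an estimated correlation). The remaining genes among the 10 largest rises were Cpne2 at 2.07, Aldh3a1 at 1.98, Ncam1 at 1.86 and Tmem100 at 1.78.

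Of 40 oxidative phosphorylation subunits 7 fell, 9 when adjusted over the list alone, with Cox8b at -0.57, Uqcrc1 at -0.58, Ndufs8 at -0.52 and Ndufa8 at -0.37. The subunit list had a median of -0.13 (camera adjusted p = 0.00044; adjusted p = 0.36 with an estimated correlation). Of 16 tricarboxylic acid cycle genes 4 fell, also 4 when adjusted over the list alone: Idh2 by 1.09, Idh3a by 0.76, Dlat, a subunit of pyruvate dehydrogenase, by 0.53 and Suclg1 by 0.48. The median of the cycle genes was -0.21 (camera adjusted p = 0.00318; adjusted p = 0.36 with an estimated correlation). Of 26 fatty acid genes 5 fell, 9 when adjusted over the list alone, with Acadl at -0.91, Echs1 at -0.79, Acads at -0.75 and Eci1 at -0.68 (median -0.28, camera adjusted p = 0.00322; adjusted p = 0.36 with an estimated correlation); a second, dimmer probe of Acadl was at 0.44. Dimmer second probes of Acads and Suclg1 were at -0.38 and -0.34, with unadjusted limma p of 0.0529 and 0.109. Of 23 regulators of mitochondrial and metabolic transcription 2 fell, 6 when adjusted over the list alone: Esrra, the oestrogen-related receptor alpha, by 0.43 (SE 0.12, adjusted p = 0.0207) and Crtc3, a coactivator of CREB, by 0.41 (SE 0.09, adjusted p = 0.00596). The regulator list had a median of -0.16 (camera adjusted p = 0.0435; adjusted p = 0.36 with an estimated correlation). Ppargc1a was at -0.28 (SE 0.18) and missed the threshold in this state.

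Of 21 genes of the LKB1-AMPK complex and AMPK-related kinases 4 fell, also 4 when adjusted over the list alone: Stk11, the AMPK subunit genes Prkab2, by 0.71 (SE 0.17, adjusted p = 0.0101), and Prkag1, by 0.41 (SE 0.11, adjusted p = 0.0176), and Mlycd, malonyl-CoA decarboxylase, by 0.75 (SE 0.24, adjusted p = 0.0467). The list's median was -0.17 (camera adjusted p = 0.0312, and adjusted p = 0.36 with an estimated correlation). Stk11, the deleted gene, is itself a member, so its part of the count and of the list call follows from the knockout. The list was not tested without it. Prkaa2, the catalytic AMPK subunit gene of muscle, was at -0.31 (SE 0.18) and missed the threshold, while its second, dimmer probe was at -0.78 with an unadjusted limma p of 0.0173. The 10 largest falls were Snai3 (-2.11), Stk11, Zfp869 (-1.30), Kcnc1 (-1.29), Tpra1 (-1.27), Dusp26 (-1.21), Slc40a1 (-1.21), Vamp5 (-1.19), Pick1 (-1.19) and Magix (-1.17). Pdk4 (0.43) and Slc2a4 (-0.32) missed the threshold. The endothelial and mural cell list shifted down again (median -0.18, camera adjusted p = 0.0276; adjusted p = 0.439 with an estimated correlation). Vwf, von Willebrand factor, was at -0.81 and Myh11 at -0.53. Ribosomal proteins were again up (median 0.16, camera adjusted p = 0.0276; adjusted p = 0.542 with an estimated correlation), with Rps24 at 0.50 and Rpl37 at 0.37. As at rest, 0 members of these 2 lists passed over all genes or over the list alone.

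Several list calls after contraction depended on samples that stood apart. Without the 3 samples low in slow-fibre genes the camera calls of the MAPK phosphatase (adjusted p = 0.1), NF-kB (0.0529), cytokine (0.0844), heat shock (0.0849) and endothelial lists (median -0.10, adjusted p = 0.108) ended. Without the 5 samples high in lymphocyte markers the ribosomal call ended (adjusted p = 0.0613), and the medians of the LKB1-AMPK and NF-kB lists were -0.06 and 0.23. The cytokine call also ended with the sample number as a block (adjusted p = 0.0638), and the cytokine and antigen presentation calls ended with cyclic loess (0.0869 and 0.0827) and with a floor in place of normexp (0.0714 and 0.0568).

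Without contracted knockout samples 1, 3 and 7, left out singly, the count of 747 was 414, 491 and 1701, and without contracted wild-type samples 1, 2 and 3 it was 497, 488 and 492. Calls that ended when 1 of the 28 arrays was left out were those of Bcl3 (21 arrays), Mlycd (14), Acads (10), Stat2 (9), Socs3 (8, highest adjusted p = 0.0897), Acadl (7), Mrc1 (7), Igtp (6), Hspb7 (5), Cxcl14, Eci1, Loxl1 and Lum (4 each) and Irf1 (2). Dusp26 and Fstl1 lost theirs without contracted wild-type sample 3, Dusp4 without contracted knockout sample 1 and Esrra without contracted knockout sample 2.

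The knockout effect was largely shared between rest and contraction: 125 of the rising genes and 134 of the falling genes were called in both states. Independent lists of those sizes would share 6.98 and 7.07, and 0 genes were called in opposite directions. Sln, Timp1, Ankrd1, Aldh3a1, Cpne2, Tmem100 and Ncam1 were among the 10 largest rises in both states, and Stk11, Snai3, Kcnc1, Vamp5, Dusp26, Slc40a1 and Magix among the 10 largest falls. Several lists called only after contraction differed about as much at rest. Relative to resting wild type, heat shock, macrophage and antigen presentation means were 0.23, 0.33 and 0.44 in resting knockout. They were 0.29, 0.41 and 0.48 in contracted knockout and 0.02, -0.02 and 0.03 in contracted wild type. For metabolic regulators the means in these groups were -0.19, -0.20 and -0.03. Others, such as immediate-early genes (0.16, 0.62 and 0.17), differed more after contraction. Across all 8391 genes the knockout differences at rest and after contraction correlated with r = 0.908. Genes are not independent replicates, and the resting and contracted knockout samples of equal number deviated together, so this is not agreement between independent samples.

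The knockout samples were not alike in these genes. The mean of the denervation list, relative to resting wild type, was 1.88, 0.36, 1.39, 1.38, 0.18, 1.85 and 0.37 in resting knockout samples 1 to 7. It was 1.99, 0.40, 1.44, 1.97, 0.12, 1.93 and 0.67 in contracted knockout samples 1 to 7, against a range of -0.42 to 0.45 over the 14 wild-type samples. Other lists followed some of the same samples. Endothelial and mural means were -0.65, 0.12, -0.31, -0.34, 0.08, -0.33 and -0.16 in resting and -0.54, 0.21, -0.09, -0.47, -0.0028, -0.34 and -0.14 in contracted knockout samples 1 to 7, against -0.12 to 0.19 in wild type. Adipocyte means were -0.99, 0.65, -0.74, 0.08, 0.51, -0.73 and -0.21 in resting knockout samples 1 to 7. After contraction they were -0.67 or lower in knockout samples 1, 3, 4 and 6 and 1.21, 1.68 and -0.30 in samples 2, 5 and 7, against -0.88 to 1.06 over the wild-type samples of both states. NF-kB means after contraction were 0.80, 0.08, 0.72, 0.70, 0.35, 0.60 and 0.26 in knockout and 0.04 to 0.59 in wild type. Markers of other tissue parts also stood apart in single samples of both genotypes. The slow-fibre list mean was -1.84 in contracted wild-type sample 4, -1.65 in resting knockout sample 4 and -0.86 in contracted knockout sample 4. The lymphocyte marker mean was 1.90 and 1.23 in resting wild-type samples 4 and 5, 2.27 in contracted wild-type sample 7, 2.23 in resting knockout sample 4 and 2.00 in contracted knockout sample 5.

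**Figure D2:**
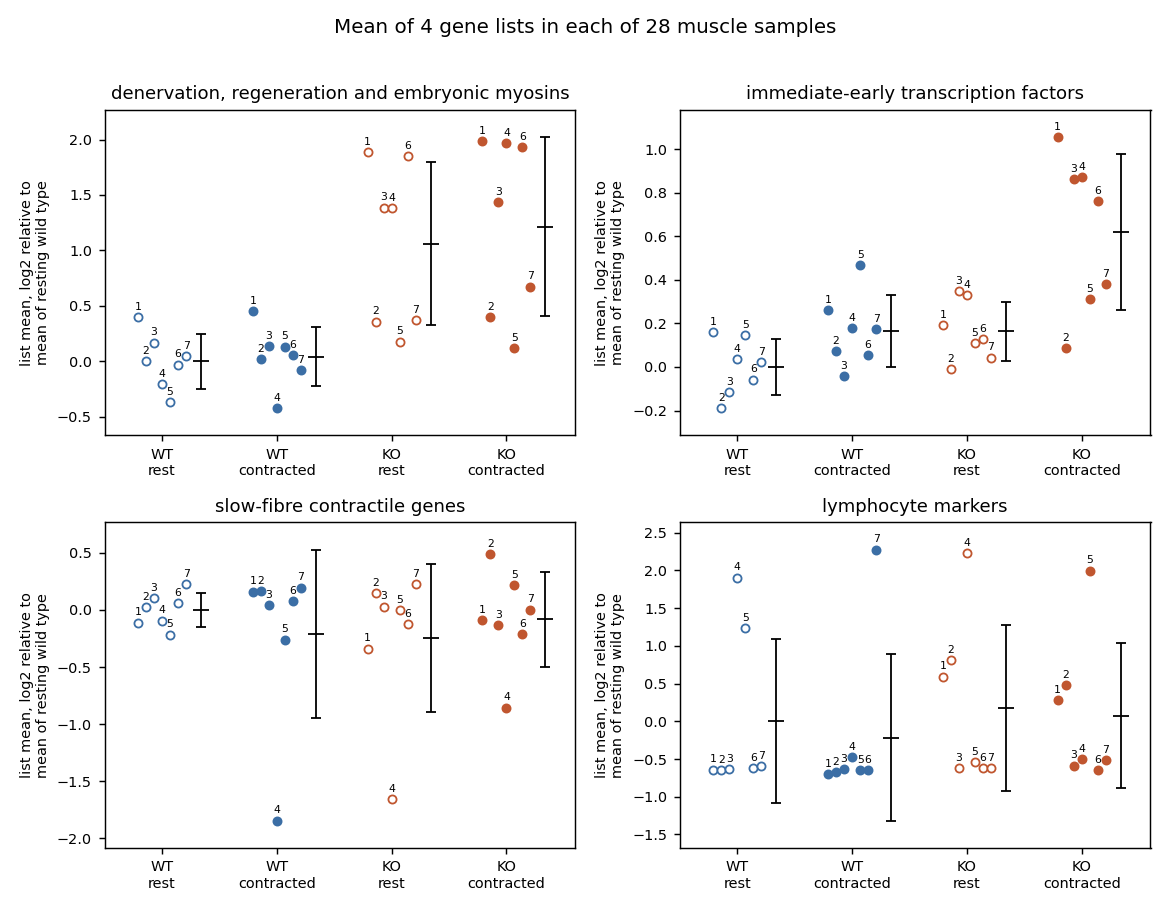
Mean log2 intensity, relative to the mean of resting wild type, of the denervation, immediate-early, slow-fibre and lymphocyte marker lists (vertical axes) in the 4 groups (horizontal axes; WT wild type, KO knockout); each circle is 1 sample with its replicate number, open at rest and filled after contraction. The denervation mean spans 0.12 to 1.99 in contracted knockout, the slow-fibre mean is -1.84 in contracted wild-type sample 4, and the lymphocyte mean reaches 2.27 in contracted wild-type sample 7.

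The third comparison asked what contraction did in wild-type muscle. No single gene passed the adjusted threshold. The 5 genes with the smallest p were all higher after contraction: Cxcl1, a neutrophil-attracting chemokine, by 1.94 (SE 0.40, limma adjusted p = 0.393), Ptx3, a secreted pattern recognition protein, by 0.79 (SE 0.21), Agt, angiotensinogen, by 0.77 (SE 0.19), Sap30 by 0.73 (SE 0.20) and Zfp296 by 0.52 (SE 0.14). Cxcl1, Ptx3, Sap30 and Zfp296 were higher in the contracted sample of all 7 equal numbers. Egr1 was 1.26 higher (SE 0.52), also in all 7 equal numbers, Fos 0.49 (SE 0.46), Nr4a3 0.34 (SE 0.15) and Ppargc1a 0.16 (SE 0.18), while Pdk4 was at -0.32 and Slc2a4 and Prkaa2 within 0.10 of 0.

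As a group, the 22 NF-kB pathway genes and targets shifted upward in wild type, with 17 members higher and a median of 0.15 (camera adjusted p = 0.000729; adjusted p = 0.411 with an estimated correlation). Socs3 was at 1.27 (SE 0.62), Icam1, an endothelial adhesion molecule, at 0.57 (SE 0.27), Selp, P-selectin, at 0.35 (SE 0.10) and Nfkbiz at 0.24 (SE 0.16). Over all genes 0 passed, and 1 when adjusted over the list alone. All 8 neutrophil markers were higher (median 0.16, camera adjusted p = 0.00635; adjusted p = 0.398 with an estimated correlation), with Il1r2 at 0.26 (SE 0.079) the 1 member that passed when adjusted over the list alone. The 23 glycolysis, glycogen and glucose uptake genes shifted up (median 0.06, 17 higher, camera adjusted p = 0.00929; adjusted p = 0.398 with an estimated correlation), with Hk2, hexokinase 2, at 0.40 (SE 0.17) and Phkg1, a phosphorylase kinase subunit, at 0.29 (SE 0.14). Fatty acid genes shifted down (median -0.11, 3 of 26 higher, camera adjusted p = 0.00635; adjusted p = 0.702 with an estimated correlation), with Acaa2 at -0.42 (SE 0.19) and Ucp3 at -0.31 (SE 0.25). So did the 14 slow-fibre contractile genes (median -0.27, camera adjusted p = 0.00929; adjusted p = 0.702 with an estimated correlation), with Csrp3, Myoz2 and Ankrd2 at -0.34, -0.34 and -0.33. In those last 3 lists 0 members passed over all genes or over the list alone. Contracted wild-type sample 4 had a slow-fibre list mean of -1.84. Without the 3 samples low in these genes the slow-fibre median was 0.06 (camera adjusted p = 0.557), and the fatty acid (median -0.06, adjusted p = 0.183), neutrophil (0.08, 0.103) and glycolysis calls (0.07, 0.0518) ended too. The glycolysis call also ended without the 5 samples high in lymphocyte markers (adjusted p = 0.0856) and the neutrophil call with a floor in place of normexp (0.0549), and with no filter on dim probes the NF-kB call alone was left of these 5. The limma count for this comparison was 0, with 89 genes at an unadjusted p under 0.05, fewer than the 420 expected by chance alone. The count of 0 therefore does not show that contraction had no effect. It was 1, Cxcl1, with array weights or with the sample number as a block.

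**Figure D3:**
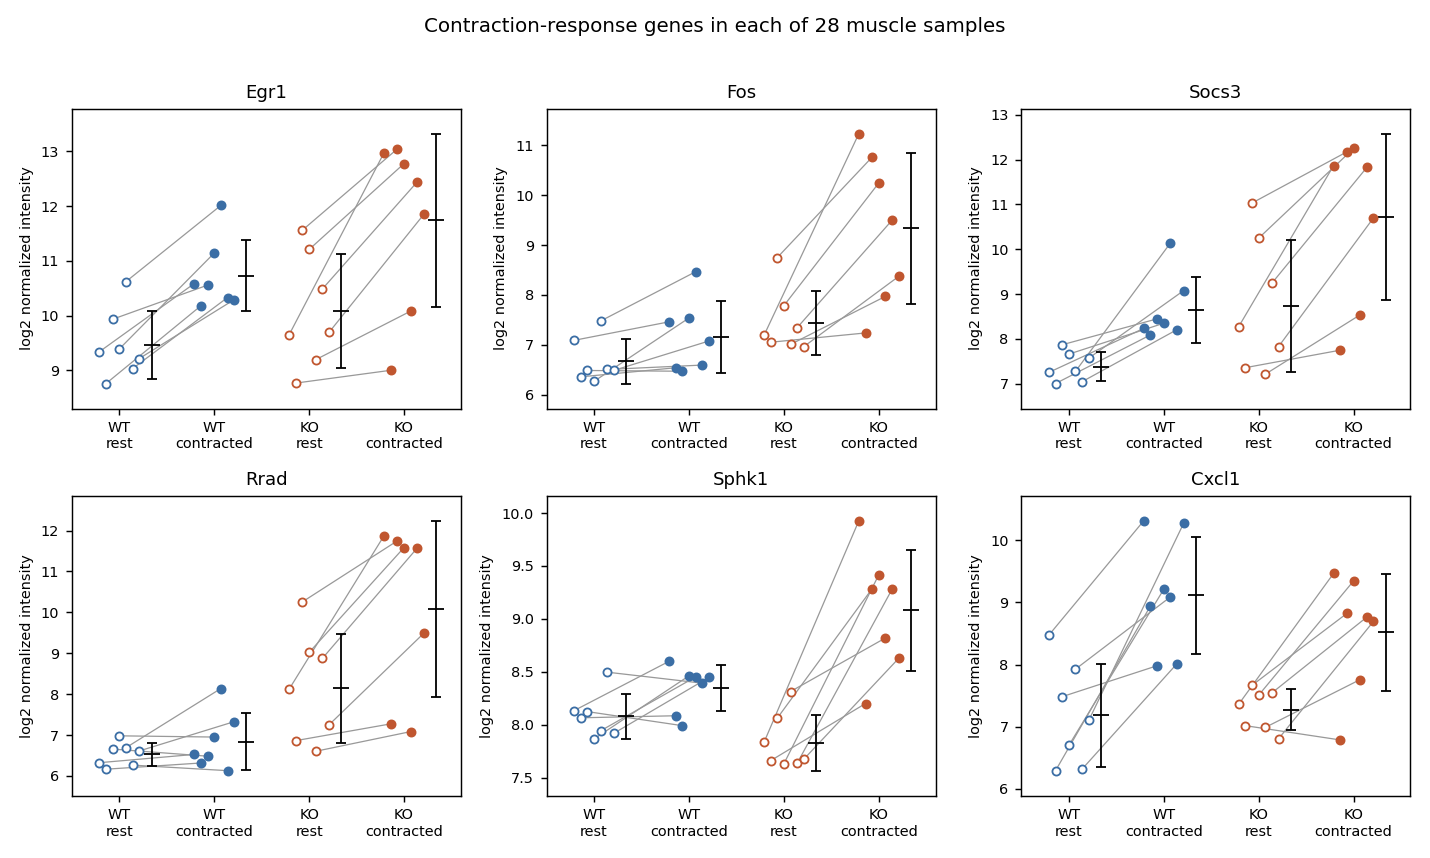
Log2 normalized intensity of Egr1, Fos, Socs3, Rrad, Sphk1 and Cxcl1 (vertical axes) in the 4 groups (horizontal axes; WT wild type, KO knockout); each circle is 1 sample, open at rest and filled after contraction, lines join samples of equal number within a genotype, and the bars give the mean and SD of 7 samples. In knockout muscle Egr1, Fos, Socs3, Rrad and Sphk1 are higher after contraction in all 7 equal numbers, and Cxcl1 in 6 of 7.

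The fourth comparison asked the same of knockout muscle. Sphk1, sphingosine kinase 1, rose by 1.25 on the log2 scale (SE 0.18, limma adjusted p = 0.00134) and was higher in all 7 equal numbers, from 7.83 ± 0.26 (SD, n = 7) to 9.08 ± 0.57 (SD, n = 7). It was the only gene of 8391 to pass without pairing the samples, and it no longer passed with only the compared groups in the fit. Without pairing 170 genes had an unadjusted p under 0.05, fewer than the 420 expected by chance alone. Samples of equal number deviated together in the knockout, so the fit with the number as a block was set beside the unblocked one: 57 genes passed there, 53 rising and 4 falling. That fit also held the wild-type arrays, blocked by number. In it 441 genes had an unadjusted p under 0.05, where 420 would be expected by chance alone. Socs3 rose by 1.99 (SE 0.31, blocked limma adjusted p = 0.0117), Rrad by 1.95 (SE 0.31, adjusted p = 0.0117), Fos by 1.89 (SE 0.30, adjusted p = 0.0117) and Egr1, a zinc finger transcription factor, by 1.66 (SE 0.24, adjusted p = 0.0117).

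Of 27 immediate-early genes 8 rose in the blocked fit and 0 in the unblocked one, where 8 rose and 1 fell when adjusted over the list alone. Beside Fos and Egr1, the blocked fit called Ier3 at 1.12 and Zfp36, an mRNA-destabilising protein, at 1.18, and the list's median was 0.22 with 22 members higher (camera adjusted p = 5.05e-17; adjusted p = 0.00157 with an estimated correlation). Of 22 NF-kB genes and targets 5 rose in the blocked fit and 4 in the unblocked one when adjusted over the list alone: Bcl3 was at 0.54, Nfkbiz at 0.56 and Selp at 0.49. The NF-kB list had a median of 0.18 (camera adjusted p = 1.27e-09; adjusted p = 0.0412 with an estimated correlation). All 13 MAPK phosphatases and feedback regulators were higher (median 0.21, camera adjusted p = 2.22e-05; adjusted p = 0.043 with an estimated correlation), among them Spred1 at 0.52 (SE 0.16) and Gadd45b at 0.45 (SE 0.17), with 0 past the threshold in either fit. With the number as a block, the adjusted p of these 3 lists with an estimated correlation was 0.0155, 0.0653 and 0.0799, so that only the immediate-early list held in both fits. The other genes among the 10 largest rises of the blocked fit were Junb at 1.21, Cish, another inhibitor of cytokine signalling, at 1.14 and Irgm2, an interferon-inducible GTPase, at 1.14. Its 4 falls were Chac1, a glutathione-degrading enzyme, at -0.60, Klhl38 at -0.36, Cyp27a1 at -0.35 and Tmem204 at -0.32. Ppargc1a rose by 0.59 (SE 0.12, adjusted p = 0.0297), Hmox1, haem oxygenase 1, by 0.55 and the metallothioneins Mt1 and Mt2 by 0.63 and 0.95, whereas Pdk4 (-0.05), Slc2a4 (-0.15), Prkaa2 (-0.08) and Nr4a3 (-0.01) missed the threshold.

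A further 8 lists shifted upward in knockout by camera and lost that call with an estimated correlation. They were the interferon (median 0.08, camera adjusted p = 3.41e-06; adjusted p = 0.135 with an estimated correlation), Schwann cell and nerve (0.19, 0.00012; estimated 0.0508), cytokine (0.08, 0.000481; estimated 0.114), angiogenesis and hypoxia (0.07, 0.00369; estimated 0.0508), neutrophil (0.19, 0.0052; estimated 0.11), satellite cell and cell-cycle (0.09, 0.00866; estimated 0.173), fibroblast and matrix (0.10, 0.0165; estimated 0.699) and denervation lists (0.13, 0.0214; estimated 0.699), each given as median, camera adjusted p and adjusted p with an estimated correlation. Egr2, which is a Schwann cell marker and also an immediate-early gene, rose by 0.51 in the blocked fit, and Bhlhe40, a hypoxia- and activity-induced repressor, by 0.88; Irf1, Igtp and Gbp2 were at 0.98, 0.73 and 0.51, Cxcl1 at 1.25 and Lcn2 at 0.48, and missed the threshold. In the unblocked fit 1 member each of the Schwann cell and angiogenesis lists passed when adjusted over the list alone, and 0 members of the other 6. The blocked fit added the fatty acid (median -0.09), slow-fibre (0.15) and oxidative stress (0.03) lists to the camera calls, with adjusted p of 0.345, 0.65 and 0.345 with an estimated correlation. Without the 5 samples high in lymphocyte markers the angiogenesis, fibroblast and neutrophil calls in knockout ended (camera adjusted p = 0.209, 0.169 and 0.373), the medians of the MAPK phosphatase, denervation and immediate-early lists being 0.13, 0.36 and 0.33. Without the 3 samples low in slow-fibre genes the denervation call ended (0.07, adjusted p = 0.241), and the MAPK phosphatase, interferon and satellite cell medians were 0.10, 0.20 and 0.16. With no filter on dim probes the Schwann cell, fibroblast and satellite cell calls ended (adjusted p = 0.122, 0.0903 and 0.303), and with a floor in place of normexp the neutrophil call (0.0567).

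The 57 blocked calls depended on the samples and on the fit: 46 genes passed with array weights in place of the block and 33 with the number as a random block, and a fit of the 14 knockout arrays alone called 0 genes with the block. Without number 6 the count was 0, without numbers 1, 3, 4 and 7 it was 5, 6, 3 and 19, and the unblocked count of 1 was 2 without resting sample 2 and 8, 4 and 4 without contracted samples 2, 5 and 7.

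The last comparison asked whether the contraction response differed by genotype, which the series names as its subject. The limma test of the difference called 0 of 8391 genes, and the count was 0 with the sample number as a block and 2 with array weights. Without the block 53 genes had an unadjusted p under 0.05, fewer than the 420 expected by chance alone. The count of 0 therefore does not show that the responses were alike. Sphk1 had the smallest p, with a response 0.98 larger in knockout (SE 0.25), followed by Slc10a6 at 0.76, Zfp82 at -0.37, Psmd9 at -0.32 and Hoxc13 at -0.27. For Fos the difference of responses was 1.39 (95% interval 0.06 to 2.73), for Egr1 0.40 (-1.12 to 1.92), for Ppargc1a 0.43 (-0.09 to 0.95), for Nr4a3 -0.35 (-0.77 to 0.08), for Pdk4 0.27, for Slc2a4 -0.22 and for Prkaa2 -0.18. Of the 57 genes called in knockout with the block, 53 had the same sign in wild type, 55 had the larger difference in knockout, and their median differences were 0.64 in knockout and 0.16 in wild type. These genes were chosen on the knockout samples, which favours the larger value there.

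Over lists, 24 of 27 immediate-early genes had the larger response in knockout, with a median difference of responses of 0.25 (camera adjusted p = 5.82e-07; adjusted p = 0.136 with an estimated correlation). The members with the smallest p were Nfil3 (0.59), Zfp36 (0.89), Ier3 (0.84) and Fos, and 0 passed over all genes or over the list alone. The list mean was higher after contraction in all 7 equal numbers of both genotypes, by 0.46 ± 0.26 (SD, n = 7) in knockout and 0.17 ± 0.09 (SD, n = 7) in wild type. In knockout numbers 1 to 7 the response was 0.86, 0.10, 0.51, 0.54, 0.20, 0.63 and 0.34, and in wild type it lay between 0.07 and 0.32. The 4 largest knockout responses belonged to numbers 1, 3, 4 and 6, which also had the 4 highest denervation means in both states. An exact two-sided permutation test of these responses gave p = 0.0175, which is 0.559 after Benjamini-Hochberg adjustment over 32 lists. Interferon-response genes (median 0.08, 14 of 17 larger in knockout, camera adjusted p = 0.000312) and MAPK phosphatases and feedback regulators (median 0.12, 12 of 13, camera adjusted p = 0.00542) shifted the same way, both at an adjusted p = 0.421 with an estimated correlation, with Irf1 at 0.88, Igtp at 0.77, Spred1 at 0.43 and Gadd45g at 0.39. Glycolysis genes shifted the other way (median -0.10, camera adjusted p = 0.0237; adjusted p = 0.421 with an estimated correlation), with Pygm, glycogen phosphorylase, at -0.35 and Phkg1 at -0.34. Slow-fibre genes had a median of 0.39 (camera adjusted p = 0.000108; adjusted p = 0.421 with an estimated correlation), with Tnnc1 at 0.61 and Tnnt1 at 0.60, which was -0.01 (camera adjusted p = 0.889) without the 3 samples low in these genes. Of these 4 lists 0 members passed over all genes or over the list alone. Without the same 3 samples the MAPK phosphatase call ended (median 0.09, camera adjusted p = 0.119) and the interferon median was 0.22. Without the 5 samples high in lymphocyte markers the glycolysis and slow-fibre calls ended (both adjusted p = 0.0837; slow-fibre median 0.18). With no filter on dim probes the interferon, MAPK phosphatase and glycolysis calls ended (adjusted p = 0.175, 0.266 and 0.175), and with a floor in place of normexp the glycolysis call (0.0551).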

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

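The tests of a single numbered pair and of neutrophils were chosen after the results were seen. So were the list responses of equal numbers with their intervals. The test of dim members and the test of the difference of responses were not chosen after the results were seen.

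The contraction response of 5 gene lists differed between the genotypes by the interaction test with camera's preset correlation, with 0 single genes called. The immediate-early list had a camera adjusted p of 5.82e-07, the slow-fibre list of 0.000108, the interferon list of 0.000312, the MAPK phosphatase list of 0.00542 and the glycolysis list of 0.0237. None of the 5 held with an estimated correlation, where the lowest adjusted p was 0.136, and fry called 0 lists.

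The larger response of immediate-early genes in knockout, 0.29 in the list mean, had a 95% interval of -0.05 to 0.63 between group means and of 0.062 to 0.52 over responses of equal numbers (exact permutation p = 0.0175, adjusted p = 0.559 over 32 lists), although the numbers were not taken to pair the wild-type samples. It is not carried by 1 numbered pair, since the difference was still 0.221 or more without any 1 of these pairs. It was uneven, with knockout responses of 0.51 to 0.86 in numbers 1, 3, 4 and 6 and of 0.10 to 0.34 in numbers 2, 5 and 7. Dim members that could not show a change in wild type do not account for it, since the 13 brighter members had a median of 0.37 and the dimmer ones of 0.11. Over the whole group more neutrophils in contracted knockout muscle stay open. The neutrophil list's own difference of responses, 0.061, had an upper 95% bound of 0.503 between group means and of 0.302 over responses of equal numbers. Both lie above the difference to be explained. In knockout numbers 3, 4 and 6 the neutrophil responses were 0.020, 0.11 and 0.015, below the wild-type mean of 0.15, which argues against neutrophils as the source there. Number 1, at 0.30, does not tell. The largest, 0.74 in number 5, went with an immediate-early response of 0.20. The genotype itself may be the source, as a hypothesis that the intervals of the immediate-early difference, of which 1 includes 0, do not settle.

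Over the 4 groups of every named gene measured, single samples were compared with the rest of their group by the gap to the nearest other sample over the group's range. Beyond the 95% critical value of Dixon's test lay samples in 41 of 532 groups, over 38 of 133 genes. Of these, 11 lay in contracted wild-type sample 4 and 5 in contracted knockout sample 7. Chance flags about 1 in 20 groups, which is 26.6 here.

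Contracted wild-type sample 4 was the lowest of its group, by log2 intensity, in Ankrd2 (9.74), Prkag1 (9.31), Sln (9.94), Stk11 (10.10), Tnnc1 (12.08) and Tnnt1 (12.27). Contracted wild-type sample 4 was the highest of its group, by log2 intensity, in Bhlhe40 (10.64), Hk2 (14.64), Rps12 (14.68), Sap30 (11.48) and Zfp296 (8.02). Contracted wild-type sample 7 was the lowest of its group, by log2 intensity, in Pick1 (9.71) and Ucp3 (7.73). Contracted wild-type sample 7 was the highest of its group, by log2 intensity, in Ndufa8 (13.33). Of the other contracted wild-type samples, sample 1 was highest in Gadd45b (9.42), sample 3 was lowest in Psmd9 (6.21), sample 5 was lowest in Ppargc1a (9.10). Resting wild-type sample 2 was the lowest of its group, by log2 intensity, in Hoxc13 (6.39), Icam1 (6.58) and Irf9 (6.49). Resting wild-type sample 2 was the highest of its group, by log2 intensity, in Crtc3 (8.69). Of the other resting wild-type samples, sample 1 was highest in Nfil3 (12.19) and Nrep (12.59), sample 5 was highest in Dusp4 (7.36) and H2-Eb1 (9.53), sample 3 was lowest in Lum (8.85), sample 4 was lowest in Flt1 (9.88), sample 6 was highest in Sphk1 (8.50). Contracted knockout sample 7 was the lowest of its group, by log2 intensity, in Zfp82 (6.19). Contracted knockout sample 7 was the highest of its group, by log2 intensity, in Cox8b (14.61), Dusp26 (9.48), Suclg1 (12.99) and Vamp5 (8.66). Of the other contracted knockout samples, sample 5 was lowest in Tmem100 (9.03), sample 5 was highest in Hmox1 (8.16), sample 3 was lowest in Rps2 (12.98), sample 4 was lowest in Tnnt1 (14.20). Of the resting knockout samples, sample 3 was highest in Ptx3 (7.59) and Vegfa (10.06), sample 4 was lowest in Tnnc1 (11.43) and Tnnt1 (12.55).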

How the results depend on the processing

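The tests with a normexp offset of 16, a floor, cyclic loess, without samples that stood apart in slow-fibre or lymphocyte genes, and all variations of the blocked fit were chosen after the data were seen. With array weights, the fixed replicate block and the random replicate block, contraction in wild type called 1 gene each in place of 0. Contraction in knockout called 1 gene, but 2 with a floor at the dim limit, 0 with only the groups compared, 46 with array weights, 57 with the fixed replicate block, 33 with the random replicate block and 4 without the 5 samples high in lymphocyte markers. Knockout at rest called 316 genes, but 207 with no filter on dim probes, 950 with array weights, 764 with the fixed replicate block, 57 at an adjusted p under 0.01 and 171 at a fold of at least 1.5. Knockout after contraction called 747, but 2616 with array weights, 1297 with the fixed replicate block, 207 at an adjusted p under 0.01 and 377 at a fold of at least 1.5. The difference of responses called 0 genes, but 2 with array weights. The blocked count of 57 in knockout was 17 with a floor, 0 in a fit of the 14 knockout arrays alone, 5 without the pairs low in slow-fibre genes and 26 without the pairs high in lymphocyte markers. Stricter thresholds lower counts by construction; for the rest the cause was not tested. Without the samples low in slow-fibre genes the counts at rest and after contraction were 233 and 515, and without those high in lymphocyte markers 340 and 728.

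Leaving out single samples gave 0 genes throughout for contraction in wild type and for the difference of responses, 1 to 8 for contraction in knockout (8 without contracted sample 2), 109 to 676 for knockout at rest (without resting knockout samples 1 and 7), 414 to 1701 for knockout after contraction (without contracted knockout samples 1 and 7), and 0 to 68 for the blocked fit (without pairs 6 and 2). Stk11 stayed between -1.42 and -1.30 at rest and between -1.54 and -1.43 after contraction. Of 45 list calls by camera, 3 held with an estimated correlation and 15 with fry, where 30 ended and 21 calls were made in all. Without the samples low in slow-fibre genes 12 of the 45 ended and 1 turned, 7 ended without those high in lymphocyte markers, 10 with no filter on dim probes, 5 with a floor, 2 with cyclic loess, 1 with the fixed replicate block and 0 with an offset of 16. The difference of Acadl after contraction was 0.44 when every probe was tested singly, because a second probe was then read, and the slow-fibre list in wild-type contraction turned to 0.062 without the 3 samples low in these genes. Over 117 called results, each of 1 gene in 1 comparison, 3825 of 4292 values under alternatives kept their call, 466 lost it (300 of them on leaving out a sample) and 1 changed sign.

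The number as a block in wild type (correlations from -0.04 to 0.55; 3 resting and 1 contracted sample of 7 correlated best with their own number) and across genotypes is a hint from the data only. Planned settings from the non-normalized table (neqc, quantile without background correction, loess or median centring without quantile) and a slide block were not run, since 21 of its 28 columns were not assigned to samples by name and no slide is given in the sources used here. Signal near background limits the dim genes: 11725 of 25697 probes were bright enough to be kept.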

Other observations

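The tests of mislabelled samples, of nerve tissue, of the immune state and of lymphoid tissue, and the interval of the slow-fibre part, were chosen after the results were seen, while the splits of the samples and the slow-fibre covariate were not.

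Several called genes lie outside the rule for named genes and were chosen after their values were seen. Csrp3, a muscle LIM protein, rose by 0.80 at rest (SE 0.22, limma adjusted p = 0.0398) and by 1.30 after contraction (SE 0.22, adjusted p = 0.0016). After contraction Chrne, the adult subunit of the acetylcholine receptor, rose by 0.94, and Myf6 and Myog, myogenic transcription factors, rose by 1.01 and 0.77 and Chrna1 by 1.32. Glycogen phosphorylase Pygm fell by 0.73 (SE 0.17) and Ugp2, which makes UDP-glucose, by 0.52, whereas Slc2a1, the glucose transporter GLUT1, rose by 0.60. Among redox genes after contraction, Srxn1, Mt1 and Mt2 rose by 1.14, 0.65 and 0.95 and Txnip and Gstm1 fell by 0.79 and 0.51.

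Without the sample number as a block, camera called 9 lists in none of the 5 comparisons. At rest and after contraction the knockout medians were -0.11 and -0.11 for 12 adipocyte markers, -0.04 and -0.05 for 15 circadian clock genes, -0.06 and -0.05 for 15 fast-fibre genes, 0.19 and 0.31 for 8 lymphocyte markers, 0.0014 and -0.02 for 19 muscle atrophy and autophagy genes, 0.14 and 0.33 for 11 myokines, 0.10 and 0.15 for 18 oxidative stress genes, -0.07 and -0.07 for 5 red blood cell markers and 0.15 and 0.11 for 12 unfolded protein response genes. Of the atrophy list 1 gene rose at rest and 3 after contraction, of the myokines 1 rose at rest and 3 rose and 1 fell after contraction, of the oxidative stress list 3 rose and 2 fell after contraction, of the unfolded protein response 1 rose at rest, and of the circadian genes 1 fell after contraction. The lowest camera adjusted p of these lists in that fit was 0.0723, for the myokines in contraction of knockout muscle, where with the block it was 0.0283 for the oxidative stress list.

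Denervation-associated genes were high in knockout to very different degrees, from 0.12 to 1.99 in the list mean. Mislabelled samples are argued against by Stk11, whose highest knockout value, 9.32, lies below the lowest wild-type value, 10.10. A missing slow part of the complex is argued against as the whole source, since the median resting difference was 1.03 with the slow-fibre mean as a covariate, which took 0.061 of 1.06 in the list mean, with an upper 95% bound of 0.171. Nerve tissue carried over is argued against by Schwann cell markers, whose resting difference had an upper 95% bound of 0.289, below the lower bound of 0.425 for the denervation list. The same knockout numbers 1, 3, 4 and 6 had the 4 lowest endothelial means at rest and the 4 largest immediate-early responses. They also had the 4 lowest adipocyte means and the 4 highest NF-kB means after contraction. For the endothelial and adipocyte lists this order did not hold in the other state. After contraction the endothelial mean of number 7, -0.14, lay below that of number 3, -0.09. At rest the adipocyte mean of number 7, -0.21, lay below that of number 4, 0.08. A difference in the makeup of the tissue or in the state of the muscle stays open, and neither was tested.

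Lymphocyte markers were high in 5 single samples of both genotypes. The immune state of the animal cannot be told apart from other sources. Of the 5 numbered pairs with a high sample 0 had both high, but only 2 of these are knockout pairs. Only in knockout did all 7 equal numbers deviate together, and no label states that they share an animal. Knockout numbers 1 and 2, below the limit of 1 used here, go with that explanation: their list means were 0.59 and 0.81 at rest and 0.28 and 0.48 after contraction, against -0.50 or lower in the knockout samples of other numbers that were not high. Lymphoid tissue carried over in some dissections is a candidate explanation: in all 7 samples with a high mean of 2 B cell genes, the mean of 4 T cell genes, at 0.46 or more, lay above that of every other sample, at 0.41 or less. B and T cells could also enter muscle together in some animals, which was not tested.

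Whether other splits of the same samples call as many genes was counted over 100 splits each. Chance can be excluded at the 0.05 level for knockout at rest, where 2 of 100 splits, the real one included, gave 316 genes or more and the highest other gave 722, and for knockout after contraction, where 2 of 100 gave 747 or more and the highest other gave 808. It cannot be excluded for the unblocked contraction in knockout, where 11 of 100 gave at least the real 1. In that set a split called 1617 genes, which points to a structure among the knockout samples that does not follow rest and contraction. For contraction in wild type and for the difference of responses the real count was 0, which all 100 splits reach whatever the data, so the splits say nothing about chance there. The highest counts among them were 126 and 1. With the block, 1 of 64 swaps of rest and contracted within the 7 pairs, the real one, gave 57 genes, and the highest other gave 15. This excludes chance for the blocked count at the 0.05 level only if equal numbers pair the samples. That pairing was read from these same data and not from a label. The number of calls of the blocked fit also rests on pair 6, without which, as in a blocked fit of the knockout arrays alone, it was 0.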
